A study of Mus musculus with 4 samples.

How the data were processed

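Total RNA from 4 esophageal tumours was extracted with Trizol and made into libraries with a TruSeq RNA kit, per the labels' protocols. The labels put 2 samples in the WT group and 2 in the group labelled S100A14 CKO, and no sample was left out. One table was used, with a row per gene and a column per library. Whether the kit kept strand, and whether messenger RNA was selected, is not given in the sources used here. The aligner, the read counter and the treatment of reads shared by paralogs or overlapping genes are likewise not given in the sources used here.

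The deposited library columns hold scaled read signal: per the file headers they carry library names only, and within each column every value is a whole multiple of one step. Dividing by that step gave whole read counts for 100% of the deposited values (tolerance 0.001). The submitters' processing notes name DESeq, with no role or version, and genome build mm9. The deposited mean and fold change columns are in log2 units, per the file headers, and the sign of the authors' fold change was read from S100a14. The p-value and adjusted p-value columns were made by the authors with a test that the file headers do not name, and they were used only where the authors' deposited table is cited. Genes with very few reads are not listed in the deposited table, so counts of genes refer to the 14157 genes it lists.

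One read equals a scaled value of 0.193, 0.318, 0.220 and 0.258 in WT replicates 3 and 6 and KO replicates 1 and 8. The median gene had 39, 22, 32 and 27 reads in these libraries, so genes near a value of 1 rest on few reads. Ribosomal RNA, 7SL and other structural RNA stayed in the table and in the scaling that the authors deposited.

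Before the data were examined, the grouping, the design, the threshold, the 37 gene lists, the rule for named genes and the first set of alternatives were written down. The design called for edgeR on counts, with limma on log2 values if the table held none. The table holds scaled values, so the limma fallback is the test reported, and edgeR and DESeq2 on the recovered reads are alternatives added after the data were seen. Values were transformed as log2(value + 1), which understates fold changes of genes with low values. Genes with a value of at least 1 in at least 2 libraries were tested (12304 genes). Limma 3.58.1 with a trended prior was run in R 4.3.3 with genotype as the sole term, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. No batch is given in the labels. A permutation of 2 against 2 libraries cannot go below an exact two-sided p of 0.333, so no permutation test was used.

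Gene lists covered keratinocyte layers, cell types, signalling pathways, the S100 family and sample quality. Lists with at least 5 tested members were tested with camera in limma (two-sided, preset correlation 0.01), with Benjamini-Hochberg adjustment over the 28 lists tested. Members were also adjusted over the list alone. Some lists share genes or tissue: muscle, fibroblast and immune genes are expressed in the normal wall of the esophagus. The preset correlation treats the genes of a list as nearly independent, and camera with an estimated correlation and fry were run as alternatives.

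Genes were named by rule: S100a14; up to 12 genes per direction past the threshold with both KO libraries on one side of both WT libraries, filled up to 5 by smallest p and then said not to pass; up to 4 members by smallest p of each list described; and, where described, S100 family genes, all of which the rule allowed. Predicted models, pseudogenes and immunoglobulin segments were counted and not named under that rule. One gene chosen by smallest p is not reported here. For a gene with 0 reads in one group, a lower bound of the fold was computed from a floor of 3 reads over that group. The interval for S100a14 is an exact binomial interval at 95%. PCR reads without molecular identifiers are not independent molecules.

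The alternatives written down beforehand were quantile normalization, limma without a trend, no filter, a pseudocount of 0.1, a minimum log2 fold change of 1, leaving out each library in turn, estimated correlation and fry. Those added later were edgeR 4.0.16 (quasi-likelihood, exact test and camera, with filterByExpr), DESeq2 1.42.0, and TMM factors from nuclear protein-coding genes. The pipeline was tested on simulated data drawn from the real libraries' means and sizes for all 14157 genes, with 200 genes changed. For KO against WT, limma recovered 3.17%, 95.5% and 100% of genes changed 4-, 16- and 64-fold, and edgeR's quasi-likelihood test 1%, 96.3% and 100%. Limma made 2.33, 9 and 15 false calls per run in these simulations. A list shifted by −1 was called in 5 of 5 runs, with 1 other list called over the 5 runs. Genes were simulated independently of one another. The shifted list, that of the NRF2 and xenobiotic response, had an estimated correlation of 0.211 in the real data. These runs therefore do not test the preset correlation.

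Gene Ontology process terms with 15 to 300 tested genes were tested with camera in the same way, chosen after the data were seen. Exon lengths came from GENCODE M21, matched by Ensembl identifier, with a length for 12281 of the 12304 tested genes. That annotation is of another build than mm9, so no coordinates are given.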

Results

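RNA was sequenced from 4 esophageal tumours of C57BL/6 mice. The tumours had been induced with 4NQO (4-nitroquinoline 1-oxide), a carcinogen that forms DNA adducts and gives squamous tumours of the mouse tongue and esophagus. A pair of libraries came from wild-type mice (WT, replicates 3 and 6) and a pair from mice labelled S100A14 CKO (KO below, replicates 1 and 8), so n = 2 per group. The labels do not state whether each library came from a separate animal, so p-values measure the spread between these samples. The deposited table listed 14157 genes, with 11132019 and 11545921 reads in WT replicates 3 and 6 and 16182109 and 11672010 in KO replicates 1 and 8. Genes annotated as ribosomal RNA took 47.0%, 72.6%, 76.4% and 50.8% of these, in the same order. The RNA of the signal recognition particle, 7SL, took 28.1% in KO replicate 8 and 13.98%, 3.21% and 5.495% in WT replicates 3 and 6 and KO replicate 1. Nuclear protein-coding genes were left with 2107060, 1289852, 1530127 and 1052423 reads. Of these, Lars2 alone took 39335, 168506, 34866 and 32076. A floor of 3 reads equals a scaled value of 0.579, 0.953, 0.660 and 0.773 in the 4 libraries, and all floors and intervals cover counting error only. KO replicate 8 stood apart: across 12304 genes its log2 values correlated with the other libraries at r = 0.769 to 0.816, against 0.908 to 0.915 among the other 3. The libraries did not group by genotype. KO replicate 1 correlated at 0.915 and 0.909 with WT replicates 3 and 6, which correlated at 0.908 with each other, and at 0.816 with KO replicate 8.

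The comparison asked which genes differ between KO and WT tumours. S100a14 itself (ENSMUSG00000042306, chromosome 3), which encodes a small EF-hand calcium-binding protein of the S100 family, had 463 and 347 reads in WT replicates 3 and 6, 0 reads in KO replicate 1 and 1 read in KO replicate 8. Its scaled value was 99.8 ± 14.8 (SD, n = 2) in WT and 0.129 ± 0.182 (SD, n = 2) in KO. S100a14 fell by 6.48 on the log2(value + 1) scale (SE 0.46, limma adjusted p = 0.0211), with both KO libraries below both WT libraries. The KO read rate of S100a14 was 0.122% of the WT rate, with a 95% exact binomial interval of 0.003085% to 0.682%. S100a14 was past the threshold neither without WT replicate 3 (adjusted p = 0.505) nor without WT replicate 6 (adjusted p = 0.361) in limma, where the lone WT library is assumed to vary like the KO pair. Its fold change stayed at −6.63 and −6.33 in those fits. Nor did it pass with a pseudocount of 0.1 (0.0541) or in edgeR's quasi-likelihood test on the recovered reads (0.115).

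Among the 12 tested genes of the S100 family list, S100a14 was the sole member past the threshold, over all genes tested and adjusted over the list alone. Of the others, S100a16 had 73.5 ± 1.61 (SD, n = 2) in WT and 45.7 ± 8.48 in KO, and S100a10, the annexin A2 partner, had 57.0 ± 8.81 in WT and 91.1 ± 8.85 in KO. S100a4 had 2.53 ± 1.33 in WT and 7.13 ± 2.31 in KO. S100a8 and S100a9, the calprotectin subunits, overlapped between the groups: S100a8 had 93.4 ± 23.8 in WT and 81.3 ± 30.4 in KO, and S100a9 had 138 ± 78.1 and 106 ± 63.9. The list as a group, which holds the deleted gene, did not pass (camera adjusted p = 0.275).

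**Figure D1:**
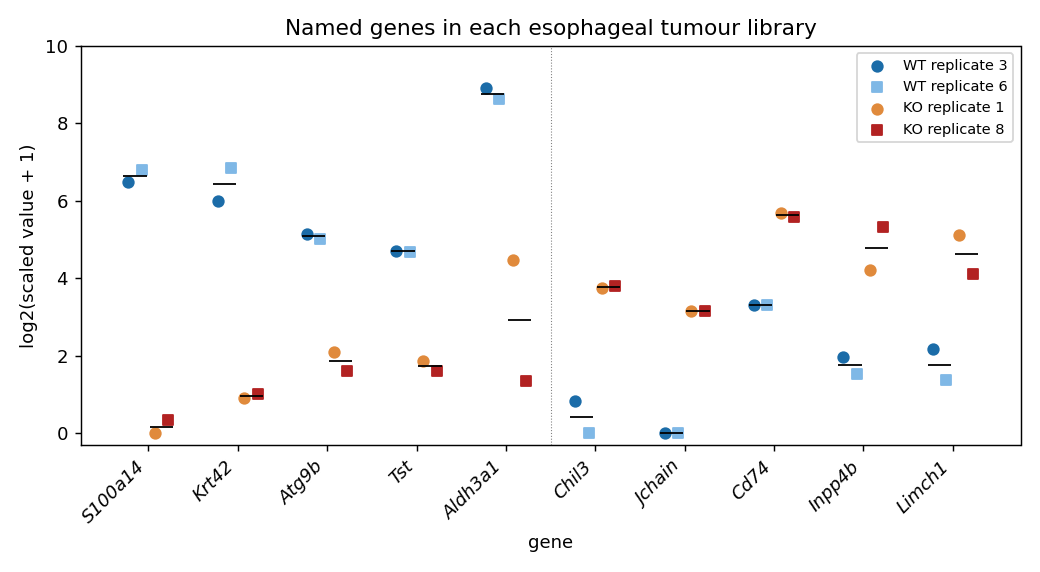
Log2(scaled value + 1) of the genes chosen by the naming rule, one point per library, with WT replicates 3 and 6 and KO replicates 1 and 8; black bars mark group means, and a dotted line parts genes lower in KO from genes higher. S100a14 lies near 0 in both KO libraries, and each other gene shown has both KO libraries on one side of both WT libraries without passing the threshold.

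Beyond S100a14 no gene passed limma's threshold: 0 of 12304 genes were higher and 1 was lower in KO. At an unadjusted p under 0.05, 201 genes were higher and 445 lower, 646 in all, where chance gives 615. On the recovered reads, edgeR's quasi-likelihood test called 0 genes (516 at an unadjusted p under 0.05), edgeR's exact test 14 higher and 30 lower, and DESeq2 22 higher and 32 lower. Both KO libraries lay on one side of both WT libraries for 33.7% of genes, where chance gives 33.3%. In simulated data of this design, with genes drawn independently, limma recovered 3.17% of 4-fold changes and 95.5% of 16-fold changes. These rates cannot be carried over to the real libraries. There S100a14 passed, but Krt42, 93.0-fold lower by group means (limma adjusted p = 0.0529), and Aldh3a1, 38.0-fold lower (0.345), did not. Changes larger than 16-fold can thus have been missed. The count moved with the library left out: limma called 203 genes higher and 307 lower without KO replicate 1, and 0 higher and 6 lower without KO replicate 8. Without WT replicate 3 or WT replicate 6 it called 0 lower.

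The genes nearest the threshold on the lower side, none of which passed in limma, included keratin, autophagy and detoxification genes. Krt42, a type I keratin, had 88.8 ± 36.1 (SD, n = 2) in WT and 0.956 ± 0.107 in KO (log2 fold change −5.46, SE 0.49, adjusted p = 0.0529). Its log2 fold change ranged from −5.88 to −5.04 over the libraries left out. Aldh3a1, an aldehyde dehydrogenase of the xenobiotic response, had 434.9 ± 61.1 in WT and 11.4 ± 13.99 in KO (−5.85, SE 0.92, adjusted p = 0.345). Its log2 fold change was −7.41 without KO replicate 1 and −4.28 without KO replicate 8. Atg9b, an autophagy gene, had 32.9 ± 2.05 in WT and 2.68 ± 0.875 in KO (−3.22, adjusted p = 0.267), and Tst, a mitochondrial sulfurtransferase, had 25.03 ± 0.356 and 2.35 ± 0.409 (−2.96, adjusted p = 0.345). Over the libraries left out, the log2 fold change ranged from −3.47 to −2.98 for Atg9b and from −3.09 to −2.84 for Tst.

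On the higher side, where immunoglobulin segments were left out by the naming rule, again none of the 5 genes passed in limma. Chil3, a chitinase-like protein of macrophages, had 0.386 ± 0.546 (SD, n = 2) in WT and 12.7 ± 0.247 in KO (log2 fold change 3.36, adjusted p = 0.345). Jchain, the joining chain of IgM and IgA, had 0 reads in both WT libraries and 36 and 31 in the KO libraries, at least 22.1-fold higher against a floor of 3 reads over the WT group (adjusted p = 0.345). Cd74, the MHC class II invariant chain, had 8.89 ± 0.0120 in WT and 49.0 ± 2.58 in KO (2.34, adjusted p = 0.442). The lipid phosphatase gene Inpp4b had 2.40 ± 0.699 and 28.4 ± 15.3 (3.02, adjusted p = 0.462), and Limch1, a regulator of non-muscle myosin, had 2.53 ± 1.33 and 25.1 ± 12.5 (2.85, adjusted p = 0.637). Over the libraries left out, the log2 fold change ranged from 2.95 to 3.78 for Chil3 and from 3.16 to 3.17 for Jchain. It ranged from 2.28 to 2.39 for Cd74 and from 2.47 to 3.58 for Inpp4b. In edgeR's exact test and in DESeq2 all 9 of these genes, the 4 lower and the 5 higher, passed.

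Of the 37 gene lists fixed beforehand, 28 had at least 5 tested members. By camera with a preset correlation of 0.01, 11 of these were higher and 10 lower in KO. With an estimated correlation 0 of the 28 passed (smallest adjusted p = 0.481), and fry, which tests the genes of a list on balance, called 0 in one direction and 2 in either direction: MHC class II genes (adjusted p = 0.0264) and the S100 family list (0.0129), which holds the deleted gene and has no other member at an unadjusted p under 0.05. Of the 21 called lists, 5 lower and 3 higher kept their call whichever library was left out. The 5 lower were the NRF2 and xenobiotic response, suprabasal keratinocyte genes, the cornified envelope, stress keratins and ribosomal proteins, the last fixed as a sample quality list. The 3 higher were macrophage, MHC class II and skeletal muscle genes.

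**Figure D2:**
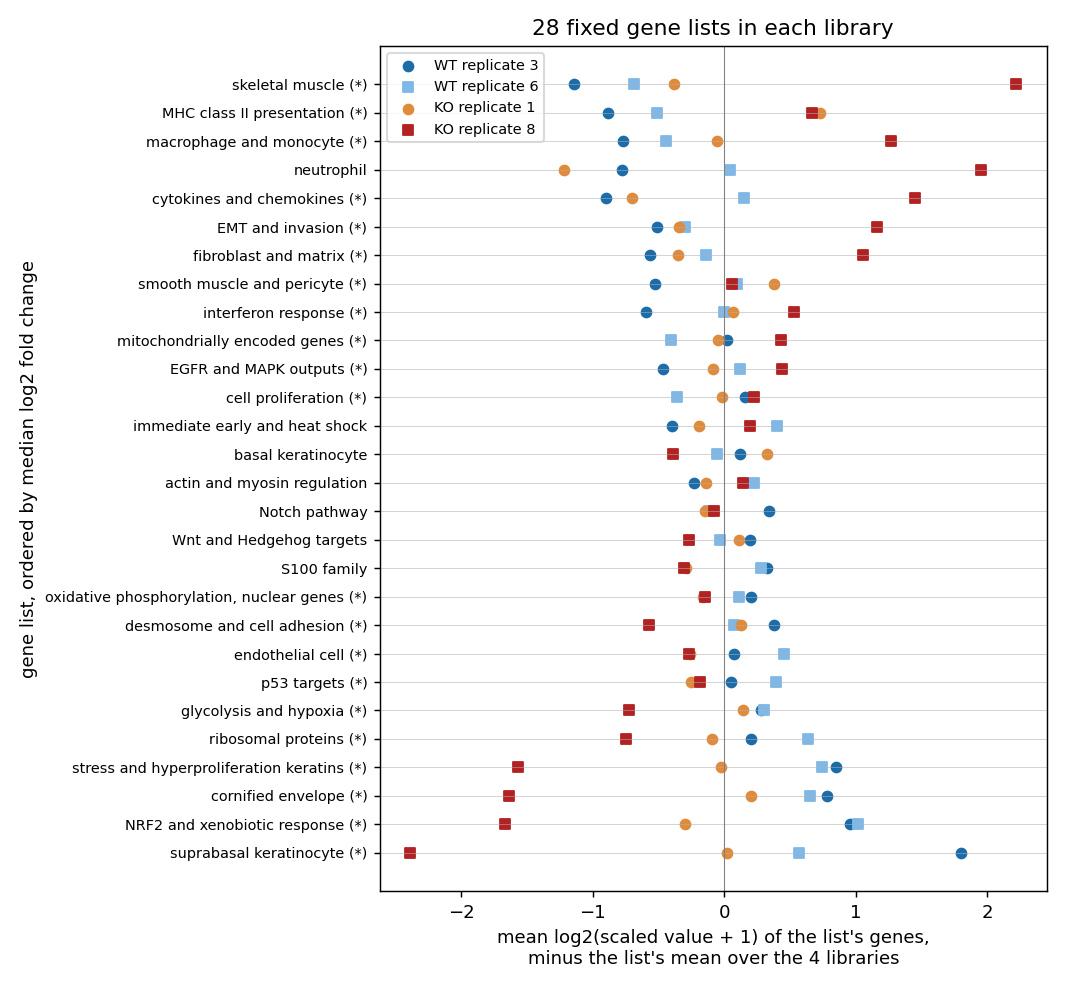
Mean log2(scaled value + 1) of each of the 28 tested gene lists (rows), one point per library, minus the list's mean over the 4 libraries (x axis, log2); an asterisk marks lists past camera's threshold. KO replicate 8 lies farthest from the WT libraries in most called lists, while MHC class II genes are alike in both KO libraries.

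Genes of the NRF2 and xenobiotic response, the antioxidant programme driven by the transcription factor NRF2, fell in the KO tumours: 25 of 26 were lower, 19 of them in both KO libraries below both WT libraries (chance 16.7%), with a median log2 fold change of −1.99 (camera adjusted p = 1.37e-15; adjusted p = 0.481 with an estimated correlation). Adjusted over the list alone, 14 members passed, against 0 over all genes tested. Gstp1, a glutathione S-transferase, had 276 ± 60.9 (SD, n = 2) in WT and 56.3 ± 37.0 in KO, and Slc7a11, the cystine transporter, had 191 ± 13.2 and 45.5 ± 28.9. Gsta3 had 13.9 ± 4.37 and 1.93 ± 1.63. The list's median was −1.37 in KO replicate 1 and −2.42 in KO replicate 8 against the WT mean.

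Genes of squamous differentiation also fell. Suprabasal keratinocyte genes were lower for 19 of 20 members (13 below both WT libraries), with a median of −2.09 (adjusted p = 2.63e-12; adjusted p = 0.481 with an estimated correlation). Adjusted over the list alone, Krt1, Krt4, Krt10 and Sbsn passed, 4 members against 0 over all genes tested. Krt4, the keratin of differentiated esophageal epithelium, had 5320 and 1258 in WT replicates 3 and 6, 387 in KO replicate 1 and 32.0 in KO replicate 8, and Krt1 had 38.7 ± 23.7 (SD, n = 2) in WT and 1.21 ± 1.71 in KO. Krt10 had 236 and 13.03 in the WT libraries and 2.64 and 1.29 in the KO libraries, and Sbsn had 199 ± 54.9 and 23.4 ± 30.1. The list's median was −0.94 in KO replicate 1 and −3.55 in KO replicate 8, while WT replicate 6 differed from WT replicate 3 by −1.17.

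Cornified envelope genes were lower for 31 of 36 members (median −1.54, adjusted p = 3.66e-10; adjusted p = 0.481 with an estimated correlation), 22 of them below both WT libraries. Their median was −0.53 in KO replicate 1 and −2.15 in KO replicate 8. Lor, the loricrin gene, had 264 ± 118 (SD, n = 2) in WT and 20.2 ± 25.3 in KO, Sprr1b had 62.1 ± 11.8 and 9.55 ± 9.50, and Flg had 32.8 ± 30.6 and 2.86 ± 1.86. Sprr2a1 went the other way, with 1.25 ± 1.77 in WT and 9.07 ± 1.17 in KO. Stress and hyperproliferation keratins were lower for 8 of 9 members (median −1.23, adjusted p = 1.31e-04; adjusted p = 0.481 with an estimated correlation). Krt16 had 2938 ± 442 in WT and 522 ± 549 in KO, and Krt6b had 6441 ± 2566 and 1159 ± 1518. Krt17 had 5554 ± 797 and 1513 ± 1674, with 2697 in KO replicate 1 and 330 in KO replicate 8, and Krt6a had 14559 ± 5748 and 4049 ± 4059. Keratin, Sprr2 and Gsta paralogs share sequence, and how shared reads were counted is not given in the sources used here, so values of single members are uncertain.

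Basal keratinocyte genes, by contrast, did not differ as a list (median 0.08, mean −0.06, camera adjusted p = 0.481). Its members were split, with 9 of 17 higher and 8 lower in KO. Outside the naming rule, Krt14 had 11878 and 8730 in the WT libraries, 7872 in KO replicate 1 and 2122 in KO replicate 8. Krt5 had 8370 and 10079 in the WT libraries, 8751 in KO replicate 1 and 1057 in KO replicate 8. Bnc1 had 14.045 ± 4.85 (SD, n = 2) in WT and 45.9 ± 25.8 in KO, and Lama3, a laminin chain gene, had 156 ± 64.6 and 487 ± 288. Krt15 had 455 and 123 in the WT libraries, 131 in KO replicate 1 and 2.58 in KO replicate 8. The list's median was −0.33 without KO replicate 1 and 0.25 without KO replicate 8. Desmosome and adhesion genes were lower for 16 of 19 members (median −0.47, adjusted p = 0.0217; adjusted p = 0.546 with an estimated correlation), among them Jup (660 ± 166 and 264 ± 197) and Perp (362 ± 36.5 and 186 ± 96.2). That list was past the threshold neither without KO replicate 8 (median −0.04, adjusted p = 0.640) nor without WT replicate 3 (0.160), nor with quantile normalization (0.121), nor with camera in edgeR on the recovered reads (0.116).

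**Figure D3:**
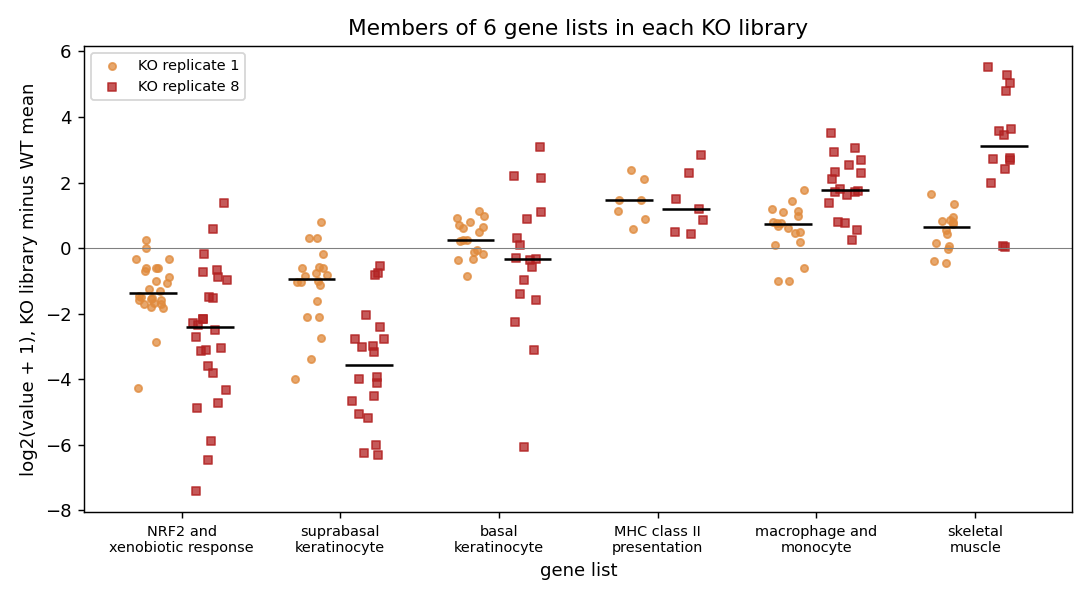
Each tested member of 6 gene lists (x axis) as log2(scaled value + 1) in KO replicate 1 (circles) and KO replicate 8 (squares) minus the WT mean (y axis, log2); black bars mark the list's median in that library. The medians of the NRF2 list are −1.37 and −2.42 and those of the MHC class II list 1.46 and 1.19, while suprabasal keratinocyte and skeletal muscle genes lie farther from 0 in KO replicate 8.

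Ribosomal protein genes were lower for 48 of 48 members, 40 of them below both WT libraries, with a median of −0.83 (adjusted p = 4.1e-13; adjusted p = 0.536 with an estimated correlation). Their median was −0.51 in KO replicate 1 and −1.17 in KO replicate 8. Over the 12281 tested genes with an exon length, log2 fold change and length had a Spearman correlation of 0.169. Shorter genes thus tended to be lower in KO. Random lists matched on length were drawn for the NRF2 list alone, so a length trend was not tested for the lists of this paragraph. Rps9 had 709.8 ± 86.7 (SD, n = 2) in WT and 256 ± 85.8 in KO, and Rpl18 had 288 ± 49.0 and 118 ± 30.5. Glycolysis and hypoxia genes were lower for 19 of 24 members (median −0.74, adjusted p = 5.08e-04; adjusted p = 0.546 with an estimated correlation), with Slc2a1, the glucose transporter GLUT1, at 455 ± 186 and 150.1 ± 81.4 and Eno1 at 1089 ± 324 and 446 ± 254. Their call ended without KO replicate 8 (median −0.31, adjusted p = 0.418). Nuclear genes of oxidative phosphorylation were lower for 31 of 36 members (median −0.27, adjusted p = 0.0165; adjusted p = 0.481 with an estimated correlation), with Uqcrc1 at 107 ± 23.2 and 52.97 ± 11.9 and Ndufv1 at 68.6 ± 2.64 and 39.7 ± 1.44. The call of that list ended without WT replicate 3, without WT replicate 6 and without KO replicate 1. Its median in those fits was −0.33, −0.40 and −0.22.

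The p53 target genes were lower for 17 of 22 members (median −0.61, adjusted p = 0.00966; adjusted p = 0.481 with an estimated correlation). Phlda3 had 147 ± 58.8 (SD, n = 2) in WT and 47.3 ± 2.76 in KO, Aen had 60.4 ± 17.96 and 24.5 ± 6.16, and Cdkn1a, the cell cycle inhibitor p21, had 52.4 ± 7.22 and 23.7 ± 13.1. Endothelial genes were lower for 11 of 13 members (median −0.60, adjusted p = 0.0139; adjusted p = 0.481 with an estimated correlation), with Vwf at 8.08 ± 1.60 and 2.96 ± 2.01 and Flt1 at 14.4 ± 4.80 and 5.91 ± 2.53. Without WT replicate 6 or KO replicate 1, neither the p53 nor the endothelial list passed (adjusted p = 0.304 and 0.164 for each). In those fits the p53 median was −0.58 and −0.65, and the endothelial median −0.30 and −0.49.

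Macrophage and monocyte genes rose: 18 of 18 members were higher in KO, 13 of them above both WT libraries, with a median of 1.19 (adjusted p = 3.66e-10; adjusted p = 0.481 with an estimated correlation). Lyz2, the lysozyme gene of myeloid cells, had 9.36 ± 0.686 (SD, n = 2) in WT and 43.2 ± 22.8 in KO. The complement genes C1qb and C1qa had 5.10 ± 3.17 against 22.5 ± 5.70 and 5.91 ± 1.53 against 17.6 ± 4.99. Cd163 had 0.193 ± 0.273 in WT and 1.32 and 8.76 in KO replicates 1 and 8. The list's median was 0.73 in KO replicate 1 and 1.77 in KO replicate 8.

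MHC class II genes rose by about the same amount in both KO libraries, with medians of 1.46 in replicate 1 and 1.19 in replicate 8. All 7 tested members were higher and 6 lay above both WT libraries (median 1.33, adjusted p = 8.22e-08; adjusted p = 0.481 with an estimated correlation). The median was 1.48 with Ciita, which had 0 reads in WT, at its lower bound. Adjusted over the list alone, Cd74 and H2-Aa passed, 2 members against 0 over all genes tested. H2-Aa had 2.27 ± 0.0651 (SD, n = 2) in WT and 17.7 ± 6.68 in KO, H2-Eb1 had 4.88 ± 2.53 and 14.6 ± 0.123, and Ciita, the class II transactivator, was at least 4.23-fold higher.

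Interferon response genes were higher for 23 of 27 members (median 0.44, adjusted p = 1.31e-04; adjusted p = 0.481 with an estimated correlation). Gbp2, a guanylate-binding protein, had 1.35 and 4.77 in WT and 6.82 and 38.4 in KO, Ddx58, the RNA sensor RIG-I, had 1.88 ± 0.481 (SD, n = 2) and 5.69 ± 0.0346, and Iigp1 had 1.32 in KO replicate 1 and 23.7 in KO replicate 8. That list did not pass without WT replicate 3 (median 0.08, adjusted p = 0.160). Cytokine and chemokine genes were higher for 14 of 18 members (median 0.97, adjusted p = 0.00716; adjusted p = 0.546 with an estimated correlation), with the alarmin gene Il33 at 5.10 ± 4.48 and 19.7 ± 6.35 and Csf1 at 2.34 ± 1.06 and 5.75 ± 1.20. Ccl2 had 1.10 in KO replicate 1 and 18.3 in KO replicate 8. The cytokine median was −0.36 without KO replicate 8 (adjusted p = 0.216) and 0.16 without WT replicate 3 (0.494). Neutrophil genes had a median of 1.03 and did not pass (adjusted p = 0.0577); it was −0.61 in KO replicate 1 and 2.52 in KO replicate 8, where Clec4d had 16.5 against 1.10 in KO replicate 1. The neutrophil list passed as higher without KO replicate 1 (3.89e-09), without WT replicate 6 (0.00809) and with no filter (0.0348), and as lower without KO replicate 8 (3.79e-04).

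Skeletal muscle genes were higher for 13 of 14 members, with a median of 1.78 (adjusted p = 2.76e-08; adjusted p = 0.481 with an estimated correlation), but unequally: 0.66 in KO replicate 1 and 3.10 in KO replicate 8. Acta1, skeletal actin, had 0.386 and 3.81 in WT, 7.04 in KO replicate 1 and 117.5 in KO replicate 8, and Tnnt3, a fast troponin, had 2.20 and 14.4 in KO replicates 1 and 8. Smooth muscle and pericyte genes were higher for 9 of 13 members (median 0.49, adjusted p = 0.0103; adjusted p = 0.536 with an estimated correlation), with Tagln at 3.64 ± 1.60 (SD, n = 2) and 12.9 ± 5.81, Rgs5 at 7.03 ± 1.75 and 18.5 ± 2.12 and Cnn1 at 0.256 ± 0.0884 and 2.74 ± 0.139. Their call ended without WT replicate 3 (median 0.19, adjusted p = 0.384) and without KO replicate 1 (0.30, 0.164).

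Genes of EMT and invasion (epithelial-mesenchymal transition) were higher for 18 of 20 members (median 0.78, adjusted p = 1.26e-04; adjusted p = 0.536 with an estimated correlation), with Tnc, the matrix protein tenascin C, at 24.98 ± 3.43 (SD, n = 2) and 49.8 ± 7.69 and Mmp13, a collagenase, at 3.30 in KO replicate 1 and 26.5 in KO replicate 8. Fibroblast and matrix genes were higher for 14 of 17 members (median 0.73, adjusted p = 3e-04; adjusted p = 0.536 with an estimated correlation), with Pi16 at 0.0965 ± 0.136 and 2.39 ± 0.267 and Lum at 1.73 ± 0.256 and 5.63 ± 2.98. Neither passed without KO replicate 8 (adjusted p = 0.640 and 0.917), where the EMT median was 0.24 and the fibroblast median −0.16. EGFR and MAPK output genes were higher for 13 of 19 members (median 0.37, adjusted p = 0.0294; adjusted p = 0.546 with an estimated correlation), among them the feedback inhibitors Spry1 (2.93 ± 1.69 and 7.75 ± 1.48) and Spry2 (6.44 ± 3.92 and 14.8 ± 3.84). Without WT replicate 3 (median −0.03, adjusted p = 0.771) or KO replicate 8 (0.0024, 0.640) that list did not pass.

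Cell proliferation genes were higher for 23 of 34 members (median 0.30, adjusted p = 0.0499; adjusted p = 0.670 with an estimated correlation), with Bub1 at 5.57 ± 1.13 (SD, n = 2) and 12.04 ± 3.18 and Birc5 at 6.79 ± 2.41 and 13.8 ± 3.06, while Pcna had 73.5 ± 6.89 in WT and 37.2 ± 5.57 in KO. Both KO libraries lay above both WT libraries for 9 members and below them for 6. Besides Pcna, those 6 held Mcm2, Mcm3, Mcm4 and Mcm7, so the list did not move as one. That list did not pass without WT replicate 6 (median 0.02, adjusted p = 0.815), without KO replicate 8 (−0.05, 0.563), with no filter (0.0992), with a pseudocount of 0.1 (0.0632) or with camera in edgeR on the recovered reads (0.0519). Mitochondrially encoded genes were higher for 10 of 13 members (median 0.38, adjusted p = 0.0317; adjusted p = 0.546 with an estimated correlation), with mt-Nd2 at 1793 ± 796 and 3405 ± 1340. They did not pass without WT replicate 6 (median 0.08, adjusted p = 0.292), without KO replicate 8 (0.25, 0.560), with no filter (0.0557), with a pseudocount of 0.1 (0.0510) or with camera in edgeR on the recovered reads (0.0631).

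The remaining tested lists did not pass. In the Notch pathway (median −0.06, adjusted p = 0.438), Notch1 had 123 ± 74.6 (SD, n = 2) in WT and 30.4 ± 3.65 in KO, and its target genes Hes1 and Nrarp had 37.5 ± 10.7 against 15.004 ± 1.17 and 18.4 ± 3.14 against 7.20 ± 0.705. Jag2, a Notch ligand, had 143 ± 51.6 and 66.9 ± 0.441. Among immediate early and heat shock genes (median 0.24, mean 5.2e-04, adjusted p = 0.543), Hspa1b passed adjusted over the list alone, with 697 ± 107 in WT and 133 ± 77.8 in KO, and Hspa1a had 110.2 ± 39.5 and 36.2 ± 30.8. That list passed as higher without WT replicate 6 (median 0.50, adjusted p = 0.00906), and its median was −0.20 without WT replicate 3 or KO replicate 8. Wnt and Hedgehog targets had a median of −0.22 (adjusted p = 0.635), with Axin2 at 7.55 ± 2.15 and 3.75 ± 0.923 and Sfrp1 at 12.4 ± 6.67 and 25.05 ± 1.90. Actin and myosin regulators had a median of −0.0012 and a mean of 0.0062 (adjusted p = 0.685), with Pfn1 at 252 ± 40.1 and 161 ± 8.46.

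Markers of other cells had too few tested genes for a list test. Among T and NK cell genes, Trbc2 had 5 and 6 reads in WT and 12 and 52 in KO, and Cd247 had 2 and 1 against 7 and 9. Of B and plasma cell genes, adjusted over the list alone Jchain passed as higher and Xbp1 as lower, with Xbp1 at 106 ± 17.1 (SD, n = 2) and 40.5 ± 18.6, and Sdc1 had 224 ± 1.73 and 123 ± 40.1. Itgax, of the dendritic and mast cell list, passed over its list alone with 0.642 ± 0.457 and 5.57 ± 1.97. Tubb3, of the nerve and Schwann cell list, passed as lower over its list alone with 54.9 ± 32.7 and 12.99 ± 3.13. The 4 erythroid genes were lower in KO, 3 of them past the threshold adjusted over the list alone, with Hba-a1 at 9.02 ± 5.66 and 1.25 ± 1.15 and Hbb-bs at 15.9 ± 10.8 and 3.29 ± 3.72. Of the 4 tested genes of the adipocyte list, 3 were higher in KO and 1 was lower. The lower one, Fabp4, had 9.43 ± 1.05 and 2.63 ± 2.48. Of the 3 tested genes of the glandular stomach list, 1 was higher in KO and 2 were lower. The lower ones were Krt8, with 2.84 ± 1.83 against 0.827 ± 0.0757, and Muc6, with 4.06 ± 0.552 against 3.43 ± 0.120. The airway and cartilage list had 2 genes in the table and 0 tested, and the thyroid and salivary gland list had 0 in the table.

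The authors' deposited table called 106 genes at an adjusted p of at most 0.05, 56 higher and 50 lower in KO. Of the 106 genes in the authors' deposited table, 83 were tested here, 83 had the same sign, and 76 had an unadjusted p under 0.05 in limma. Those calls rest on the same 4 libraries, so a shared sign was due. All 44 genes called by edgeR's exact test on the recovered reads were among the authors' calls. The exact test and the authors' deposited table are thus not separate support for a gene. The authors' deposited table gave S100a14 a log2 fold change of −9.38 (adjusted p = 1.4e-15) and Krt42 one of −6.50 (3.51e-11). The genes higher in KO with the smallest adjusted p in the authors' deposited table were the immunoglobulin genes Igkc (9.72, 3.58e-09) and Ighm (9.50, 3.58e-09). The authors' deposited table also called Aldh3a1 (−5.24, 0.00296), Krt1 (−4.92, 7.42e-05), Krt10 (−5.96, 5.04e-04), Cd74 (2.46, 0.00900) and H2-Aa (2.94, 0.0174). By list, the authors' deposited table called 7 skeletal muscle genes higher, 2 MHC class II genes higher, 2 suprabasal and 2 cornified envelope genes lower, and 1 NRF2 gene lower.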

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

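The fits on recovered reads and the protein-coding scaling were chosen after the data were seen, and the other alternatives were planned. S100a14 kept its direction in all 12 alternatives (adjusted p 4.02e-16 to 0.505). It was past the threshold neither with a pseudocount of 0.1 (−9.04, adjusted p = 0.0541), nor in edgeR's quasi-likelihood test (−9.38, adjusted p = 0.115), nor without either WT library. It ranged from −6.65 to −6.32 over the libraries left out. With one library left out, the lone library of a group is assumed to vary like the other group.

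The number of genes lower in KO was 2 with no filter (S100a14 and Krt42), 0 with a pseudocount of 0.1, 0 in edgeR's quasi-likelihood test, 30 in edgeR's exact test and 32 in DESeq2, and the number higher was 14 and 22 in the last 2. Over the libraries left out it ranged from 0 to 203 higher and from 0 to 307 lower. The cause was not tested, apart from fewer samples in the last fits. Lists higher in KO numbered 5 to 11 over the libraries left out, and 0 with an estimated correlation and with fry, as did lists lower in KO (0 and 0). Camera in edgeR on the recovered reads gave no value for MHC class II genes, which had fewer than 5 members after its filter. Fry does not compare a list with other genes. The cause of the loss with an estimated correlation was not tested.

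Reversals came only from left-out libraries, with fewer samples. The medians ranged from −0.33 to 0.25 for basal keratinocyte genes, −0.23 to 0.31 for Notch, −0.61 to 2.52 for neutrophil, −0.36 to 2.22 for cytokine, −0.20 to 0.50 for immediate early, −0.26 to 0.31 for actin and −0.35 to 0.0403 for Wnt genes. Those of the called proliferation, EGFR and fibroblast lists also crossed 0 (−0.05 to 0.55, −0.03 to 0.92 and −0.16 to 1.665). Among genes, S100a8 ranged from −0.61 to 0.16, S100a9 from −1.04 to 0.26, Il1b from −1.83 to 4.18 and Cxcl2 from −1.72 to 4.00. Of the 21 called lists, 8 lower and 5 higher were called in the same direction without KO replicate 8. Quantile normalization and the protein-coding scaling moved the median of all genes by −0.0739 to 0.0485 per library. No paired analysis was possible because the groups share no replicate numbers (3 and 6 against 1 and 8). Depth limits genes near a value of 1, which rest on 3 to 5 reads.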

Other observations

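All tests in this part were chosen after the results were seen. Immunoglobulin genes were seen in the KO libraries alone: 33 genes, 7 constant and 26 variable, had 0 reads in both WT libraries, 384 reads in KO replicate 1 and 791 in KO replicate 8, at least 400.1-fold more against a floor of 3 reads over the WT group. Igkc had 65 and 140 reads in KO replicates 1 and 8, Ighm 67 and 110, Igha 99 and 41, and Ighg1 10 and 259. None of the 4 passed in limma (adjusted p = 0.201 for Igkc, 0.172 for Ighm, 0.243 for Igha and 0.910 for Ighg1), and reads of similar immunoglobulin genes are uncertain. With each library left out in turn, the log2 fold change ranged from 3.935 to 5.21 for Igkc and from 3.98 to 4.875 for Ighm. It ranged from 3.53 to 4.51 for Igha and from 1.68 to 6.08 for Ighg1. Igkc, Ighm and Igha passed in edgeR's exact test (3.75e-08, 1.84e-08 and 4.26e-07) and in DESeq2 (5.44e-05, 8.52e-05 and 4.09e-04), and the authors' deposited table called all 4. Of 487 Gene Ontology processes, 8 were higher and 20 lower in KO by camera in limma, and 0 with an estimated correlation (smallest adjusted p = 0.980). Nucleosome assembly genes were lower (70 genes, median −0.70, adjusted p = 2.28e-07), with Hist1h2bp at 14.99 ± 0.0863 (SD, n = 2) in WT and 2.53 ± 1.395 in KO, Hist1h2be at 128 ± 41.6 and 43.0 ± 11.6, and H2afy2 at 8.30 ± 4.10 and 0.258 ± 0.364. Genes of the response to interferon beta were higher (22 genes, median 1.0, adjusted p = 4.58e-06), with Ifi204 at 2.24 ± 0.923 and 18.8 ± 13.5 and Irgm2 at 0.318 ± 0.449 and 4.21 ± 3.16.

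Trp53, the p53 gene, had 54.2 and 50.5 in the WT libraries and 6.16 and 14.7 in KO replicates 1 and 8 (log2 fold change −2.33, limma adjusted p = 0.836). The homeobox gene Dlx2 and the zinc finger gene Sp9 had 0 reads in both KO libraries, at least 21.1-fold lower for Dlx2 and at least 29.0-fold lower for Sp9 (limma adjusted p = 0.368 and 0.376). Dlx2 and Sp9 passed in edgeR's exact test (7.56e-05 and 5.86e-05) and in DESeq2 (0.0175 and 0.00539). Their log2 fold changes ranged from −3.12 to −3.05 for Dlx2 and from −3.94 to −2.88 for Sp9 over the libraries left out. AY036118, annotated as a long noncoding RNA, had 418510 reads in WT replicate 6 and 0 in each of the other libraries. Lars2 was also highest in WT replicate 6, with 168506 reads against 39335, 34866 and 32076 in WT replicate 3 and KO replicates 1 and 8. Whether these reads are transcripts of AY036118 and Lars2 was not tested. KO replicate 8 alone had high values of Il1b (191), Cxcl2 (97.9) and Hmga2 (37.6), against at most 21.3 for Il1b, 10.5 for Cxcl2 and 1.32 for Hmga2 in the other libraries.

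The NRF2 and xenobiotic genes were lower in both KO libraries. Fewer keratinocytes in the KO pieces would lower basal keratinocyte genes alike. The NRF2 median minus the basal median was −1.62 in KO replicate 1 and −2.09 in KO replicate 8, with upper bootstrap bounds of −1.02 and −0.929. These values argue against it for these libraries only. All bootstrap bounds in this part come from resampling genes within a single library. They treat genes as independent and hold no spread between tumours. A trend with exon length and level was also argued against: 0 of 10000 lists matched on both had so low a median (lowest −0.84 against −1.99). Fewer differentiated squamous cells may still account for it, since in the KO libraries the NRF2 and suprabasal medians were not separated (difference −0.435 with bounds −0.857 and 0.266 in KO replicate 1, and 1.13 with bounds −0.184 and 2.38 in KO replicate 8), although between WT replicates 6 and 3 the suprabasal median differed by −1.17 and the NRF2 median by 0.000174, which goes against it; a KO effect on the NRF2 programme and differences between tumours stay open too.

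Immunoglobulin reads were present in both KO libraries and in neither WT library. Depth does not account for this, since 1161 reads were due in WT at the KO rate. For more non-epithelial tissue of every kind, fibroblast, endothelial and smooth muscle genes changed by a median of 0.422 in KO replicate 8 (upper bootstrap bound 1.09). In KO replicate 1 the median was −0.117 (0.243), so these genes showed no clear rise there. The least immunoglobulin rise was 9.14 and 7.87 on the log2 scale. That rise is of a sum over a floor, and the medians are of single genes on the log2(value + 1) scale. The sum holds all 33 immunoglobulin genes listed, with no choice by WT reads. The group itself was taken up after its lack of WT reads was seen. The gap between such unlike measures cannot decide the question. B or plasma cells of the KO tumours may be the source, with Jchain at 36 and 31 reads. Of the same list Xbp1 (106 and 40.5) and Sdc1 (224 and 123) were lower in KO. Both were high in the WT libraries, which had 0 reads of Jchain and of the immunoglobulin genes. Their signal therefore did not follow plasma cell reads and decides nothing about that source. A KO effect and differences between single tumours cannot be told apart, since 2 against 2 gives no exact p under 0.333.

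KO replicate 8 stood apart from the other libraries. Structural RNA and shallow depth do not account for all of it: over nuclear protein-coding genes thinned to 1052423 reads, its highest r was 0.793, against at least 0.890 among the other 3. Fewer keratinocytes alone would lower both layers alike, but its suprabasal median minus its basal median was −3.23 (upper bound −1.93). For the muscle genes, skeletal muscle in the piece, a tissue of the wall of the mouse esophagus, is a candidate source. Of these genes 12 of 14 were highest in KO replicate 8 by at least 1 on the log2 scale, with Acta1 at 117.5. That count restates the pattern and does not test the source. A less differentiated tumour and other differences between tumours were not tested and may contribute.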
